A study of Rattus norvegicus with 13 samples.

How the data were processed

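Gene expression was measured on Affymetrix Rat Gene 1.0 ST arrays in cultured cells of adult Sprague Dawley rats. The cells were skin-derived precursors (SKPs), dermal cells grown in culture from 3 skin regions, and mesenchymal stromal cells (MSCs). The series holds 13 arrays, with 3 independent isolates each of dorsal, ventral and facial SKPs and 4 of MSCs, and all cells had been passaged 2 times per the labels. RNA was extracted with Trizol followed by RNeasy columns, amplified, and labelled with the manufacturer's kits for whole transcripts. The tissue the MSCs came from, their culture medium and that of the SKPs are not given in the sources used here.

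The deposited values are log2 expression values that the authors made with RMA (background subtraction, quantile normalisation and summary over probes) at the level of core genes in Affymetrix Expression Console. The submitters' processing notes also name limma, and no versions are given in the sources used here. The values were used as deposited. Array medians lay between 4.91 and 5.01, the lowest value was 0.78 and the highest 14.06 (log2). For arrays there is no count of reads, and the number of arrays limits the precision. P-values of single genes measure the spread between isolates that the labels call independent. Those of the gene lists below compare the genes of a list with all others. At a preset correlation they largely leave out variation between isolates that the genes of a list share.

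The table held 29215 probe sets. Of these, 15310 carried exactly 1 gene symbol, 323 carried several and 13582 had no name in the annotation given, and the last 2 kinds were left out. Symbols were updated through Entrez identifiers for 15279 probe sets and through transcript accessions for 6, 25 kept the symbol of the annotation, and 2 symbols changed. Where a gene had several probe sets (527 genes), the one with the highest mean over all arrays was used, which left 14506 genes. No gene was removed for a low level. The annotation of assembly GRCr8 served for names alone, so no positions are given.

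Group means of dorsal, facial and ventral SKPs and MSCs were fitted for each gene over all 13 arrays with limma 3.58.1 in R 4.3.3, with moderated standard errors. From that fit 8 comparisons were drawn: SKPs (mean of 3 regions) minus MSCs, each region minus MSCs, the 3 differences between regions, and facial minus trunk SKPs, where trunk is the mean of dorsal and ventral. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison. These tests were two-sided. Differences are log2 with the standard error (SE) of the fit, and levels are log2 means with the standard deviation (SD) over the arrays of a group.

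Genes were named by a rule. For each comparison these were the 10 genes with the largest differences in each direction among those called with a log2 difference of at least 1, no overlap between the arrays of both sides, and a level above background on the higher side. Added to these were the 2 to 4 called members of each gene list with the largest differences, and a fixed set (Sox2, Nes, Snai2, Twist1, Ngfr, Pax3, Sox9, Vcan, Crabp1, Cd44, Thy1, Vcam1). In some comparisons only part of the genes that the rule gives are named. Background was set at the 25th percentile of a group's means, because only 53 genes had the symbol Olr for olfactory receptors, by which the rule counted them, where 100 were asked for. The annotation names most of these genes Or, which was seen later and led to the added filter below. It was 3.84 in dorsal SKPs, 3.84 in facial SKPs, 3.79 in ventral SKPs and 3.83 in MSCs.

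Gene lists (33) were written from general knowledge: 6 for position along the body (anterior, central and posterior Hox genes, craniofacial patterning factors, somite and dorsal dermis factors, lateral plate and ventral body wall factors), 6 for identity and lineage (neural crest factors, dermal papilla and dermal sheath markers, bone, cartilage and fat lineage markers, stromal surface markers), 8 for other cell types (Schwann and glial, melanocyte, neuronal, keratinocyte, macrophage and leukocyte, endothelial, skeletal muscle, smooth muscle and pericyte markers) and 13 for processes (cell cycle, interferon-stimulated, cholesterol synthesis, fibrillar and dermal matrix, hypoxia and glycolysis, actin and serum response, Wnt, FGF and EGF, BMP and TGF-beta, Hedgehog and Notch pathway genes, inflammatory cytokines and chemokines, MHC class II genes). Of their 518 distinct genes, 445 were measured. Lists were tested with camera (limma) at a preset correlation of 0.01 between genes and adjusted over the lists of a comparison. An estimated correlation and fry (limma) were the alternatives. A median per list is the median log2 difference of its measured members. The fit, the threshold, the lists, the named gene rule and the alternatives, apart from 3 named below, were chosen before the data were examined.

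Separation of groups was the mean distance (1 minus Pearson r over genes) between arrays of different groups minus that within groups, with a one-sided exact permutation test over all relabellings. Its alternatives were Euclidean distance, the 1000 genes with the highest variance, the filter at background, a block for the sample number, and each array left out in turn. Simulated data with the same variances and group sizes were used to test the fits over 10 runs with 200 changed genes. For SKPs minus MSCs, 40.6% of genes shifted by 0.5 (log2), 89.4% of those shifted by 1 and 98.2% of those shifted by 2 were called, and 4.82% of calls were false. For facial minus dorsal SKPs these shares were 11.9%, 75.4% and 95.0%, with 3.73% false. Camera called a shifted list of 20 genes in 10 of 10 runs and 3 of 330 unchanged lists. Genes were simulated independently of each other, so these runs do not show how often lists of correlated genes are called falsely. The separation test passed in 10 of 10 runs with an effect and in 1 of 10 without.

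Alternatives changed one choice at a time: the fold and p thresholds, filters at the background and the median level, all probe sets, the mean of a gene's probe sets, 3 further scalings (median centring, quantile normalisation again, cyclic loess), array weights, a trend and robust variance, a fit on the groups compared alone, a block for the sample number, and each array left out in turn. After the data were seen, 3 were added: the mean of the leukocyte markers on each array as a covariate (the leukocyte signal), dorsal array 3 and facial array 3 left out together, and a filter at the 95th percentile of 1105 olfactory receptor genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.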

Results

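Expression of 14506 genes was compared in 9 arrays of SKPs, taken from dorsal, facial and ventral skin (3 isolates each), and 4 arrays of MSCs, all from adult rats. SKPs are sphere-forming dermal precursors with neural crest-like properties, and the MSCs served as another adult mesenchymal cell. The series title poses the question: whether such a precursor arises alike from skin of distinct developmental origins. Facial dermis comes largely from the neural crest, dorsal trunk dermis from somites and ventral trunk dermis from lateral plate mesoderm. Levels are log2 values with the SD over the isolates of a group, n = 3 for each SKP region and n = 4 for MSCs.

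SKPs and MSCs stood apart as whole profiles, and within SKPs the ventral arrays did too. Correlated across genes, which are not independent replicates, SKP arrays of different regions had a mean r of 0.967 (dorsal with facial), 0.971 (facial with ventral) and 0.972 (dorsal with ventral). MSC arrays had a mean r of 0.938 with dorsal, 0.931 with facial and 0.937 with ventral SKPs, and 0.979 with each other. Within a region the mean r was 0.995 for ventral, 0.982 for facial and 0.972 for dorsal SKPs, and the mean r of dorsal arrays with each other was close to that with ventral ones. Dorsal array 3 lowered it, since dorsal arrays 1 and 2 had r = 0.988, above any dorsal array with a ventral one (highest 0.983). Facial arrays overlapped with other regions: their lowest r with each other was 0.976. That was below their highest r with a dorsal (0.984) or ventral array (0.979). Ventral arrays had an r of at least 0.994 with each other, above any with a dorsal or facial array. Distances between SKP and MSC arrays exceeded those within both kinds by 0.0386 (one-sided exact permutation p = 0.0014, the smallest that 715 splits can give). Distances between regions exceeded those within regions by 0.013 (one-sided exact permutation p = 0.00357, the smallest that 280 splits can give). The spread within a group was smallest in ventral SKPs, with a median SD of 0.12, against 0.15 in facial SKPs, 0.19 in MSCs and 0.20 in dorsal SKPs. Dorsal array 3 stood apart: 9.55% and 7.67% of genes differed by over 2-fold from dorsal arrays 1 and 2, against 2.07% between these. Its hypoxia and glycolysis genes had a mean of 10.12 (8.89 and 8.88 on the others), its matrix genes 9.06 (10.78 and 10.81) and its cell cycle genes 5.26 (7.37 and 6.91). Facial array 3 differed less strongly: 4.23% and 4.05% of genes lay over 2-fold from facial arrays 1 and 2, against 2.28% between these. MSC arrays fell into 2 pairs: 0.76% of genes differed by over 2-fold between arrays 1 and 2 and 2.25% between arrays 3 and 4, against 4.61% to 6.58% across the pairs.

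**Figure D1:**
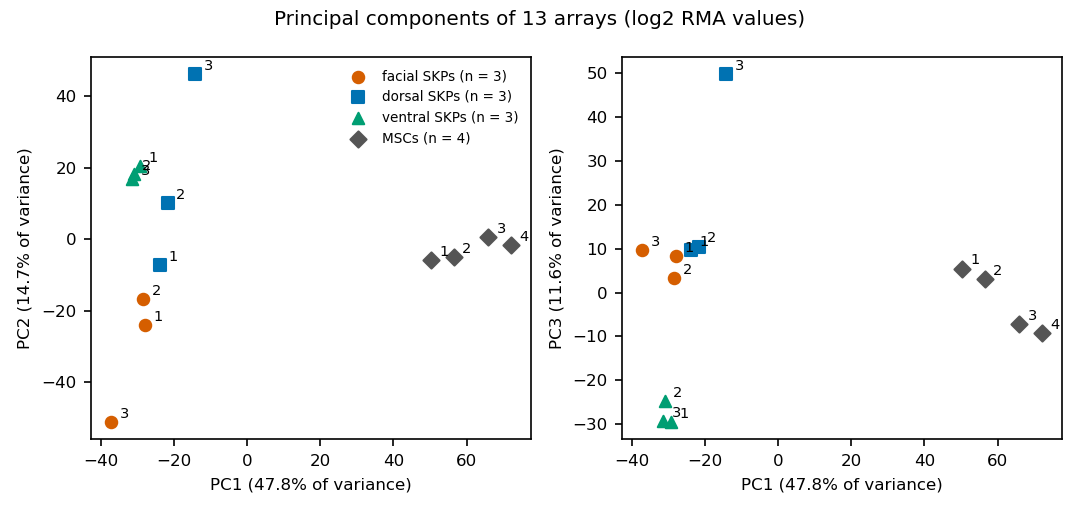
Each point is 1 array placed by the first principal components of all 14506 genes, and the axes carry the percent of variance. The first component (47.8%) parts the 9 SKP arrays from the 4 MSC arrays, and the second holds 14.7%.

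Among the single genes with the largest differences between SKPs and MSCs were 3 matrix metalloproteinases and the contractile genes Tagln and Cnn1. Collagenase 3 (Mmp13) was 347-fold higher in SKPs, at 12.51 ± 0.44 in dorsal, 12.64 ± 0.66 in facial and 12.65 ± 0.14 in ventral SKPs against 4.16 ± 1.20 in MSCs (log2 difference 8.44, SE 0.42, adjusted p = 1.25e-07). The stromelysins Mmp10 (7.48, SE 0.24, adjusted p = 7.81e-09) and Mmp3 (5.61, SE 0.45, adjusted p = 4.2e-06) rose with it. So did decorin (Dcn), a small matrix proteoglycan (7.55, SE 0.59, adjusted p = 3.15e-06), and the secreted guidance factor Sema3a (5.58, SE 0.10, adjusted p = 3.69e-11). Further down the same side stood the thyroid hormone deiodinase Dio2 (6.40), carbonic anhydrase 2 (Car2, 5.75), Efemp1 (5.54), ceruloplasmin (Cp, 5.52) and Sez6l (5.28). The actin-binding protein transgelin (Tagln) was 170-fold lower in SKPs, with regions between 4.52 ± 0.34 (ventral) and 5.04 ± 0.60 (dorsal) against 12.26 ± 0.62 in MSCs (log2 difference -7.41, SE 0.28, adjusted p = 1.67e-08). The other large decreases were Fhl1 (-5.79), Akap12 (-5.62), Cyp1b1 (-5.52), the collagen receptor subunit Itga11 (-5.43), Smoc1 (-5.38), the cartilage proteoglycan aggrecan (Acan, -5.23), calponin 1 (Cnn1, -5.09), Mfap5 (-5.06) and Tgfb3 (-4.94). These 20 genes were chosen for having no overlap between the 9 SKP and 4 MSC arrays. Mmp10, Dio2 and Car2 were below background in MSCs, so the size and rank of their differences are not resolved. The same holds below for Dkk2, Cdh6, Cd36, Hapln1 and Usp18, and for Lgr5, Phex, Hoxa11 and Il6, which were below background in SKPs.

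Of the fixed set of genes, Crabp1, Sox2 and Twist1 were higher than in MSCs in all 3 regions, and Sox9 was not measured. The retinoid-binding protein Crabp1 (4.87, SE 0.67, adjusted p = 0.000236), the stem cell factor Sox2 (1.70, SE 0.24, adjusted p = 0.00031) and the neural crest factor Twist1 (1.72, SE 0.29, adjusted p = 0.000953) were higher in 9 of 9 SKP arrays than in any MSC array. Sox2 stood at 7.06 ± 0.38 in dorsal, 6.78 ± 0.66 in facial and 7.08 ± 0.43 in ventral SKPs against 5.27 ± 0.30 in MSCs. The neurotrophin receptor Ngfr rose by 1.09 (SE 0.21, adjusted p = 0.00228), with overlap between single arrays. Nestin (Nes) did not pass (-0.01, SE 0.41, adjusted p = 0.992), since it stood at 7.54 ± 0.10 in ventral SKPs, 4.31 ± 0.73 in dorsal SKPs, 4.79 ± 0.36 in facial SKPs and 5.55 ± 1.15 in MSCs. Versican (Vcan, 0.07, SE 0.30, adjusted p = 0.9) and the stromal surface proteins Cd44 (0.25, SE 0.14, adjusted p = 0.23) and Thy1 (-0.51, SE 0.38, adjusted p = 0.376) did not pass either. The adhesion molecule Vcam1 rose (1.51, SE 0.45, adjusted p = 0.028), with facial SKPs alone called, and lost the call without MSC array 3 (0.0947) or MSC array 4 (0.1), with 0.00785 to 0.132 over the alternatives. Snai2, a factor of epithelial-mesenchymal transition, fell (-1.22, SE 0.36, adjusted p = 0.0271). That call was lost without MSC array 2 (adjusted p = 0.0643), MSC array 3 (0.0692), MSC array 4 (0.0954) or ventral array 3 (0.0504), and its adjusted p ran from 0.00552 to 0.11 over the alternatives.

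**Figure D2:**
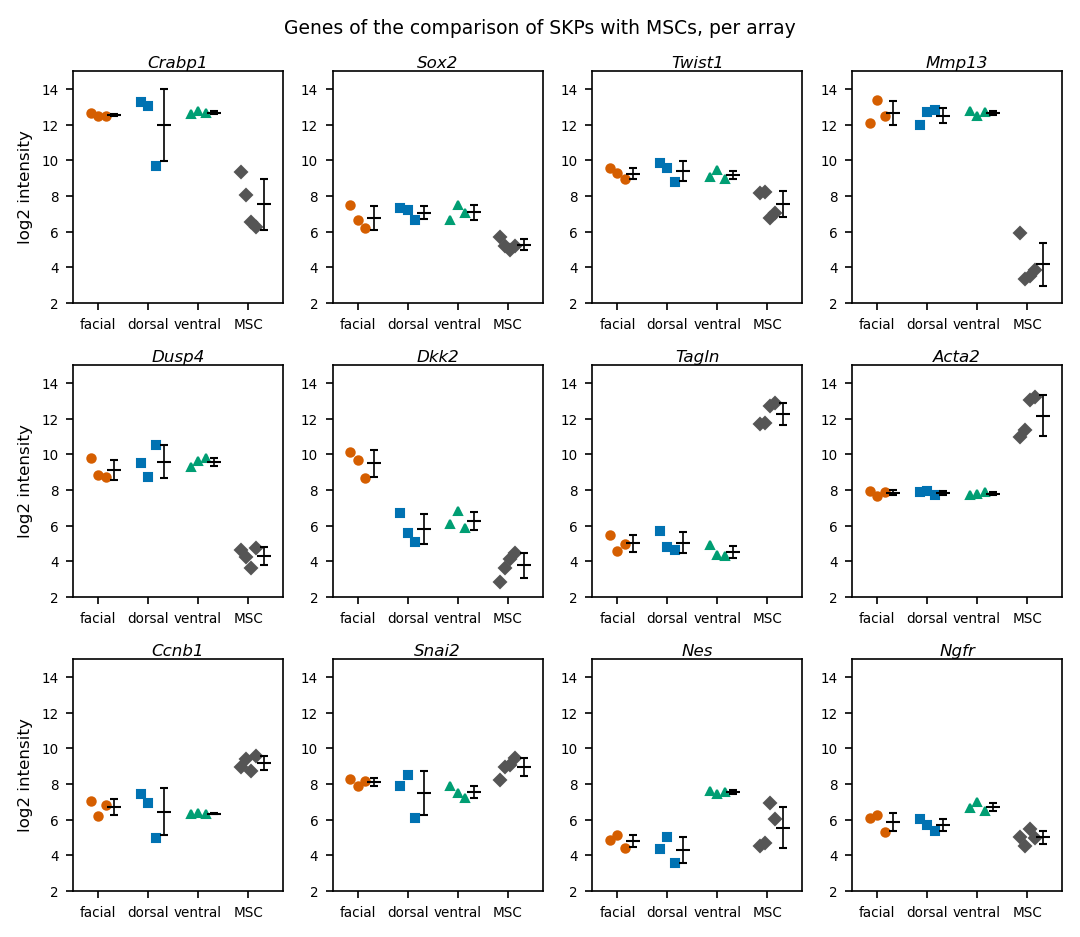
Points are single arrays and bars are the mean and SD of each group (3 arrays per SKP region, 4 of MSCs) for 12 genes, in log2 expression. Tagln and Acta2 are lower and Mmp13 and Dusp4 higher in all 9 SKP arrays than in the 4 MSC arrays, and Nes is high in ventral SKPs.

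Actin and serum response genes were the list with the smallest p: all 17 measured members fell in SKPs, and 17 also when adjusted over the list alone, with a median of -2.30 (camera adjusted p = 6.85e-14, and adjusted p = 0.241 with an estimated correlation, 3.09e-15 to 0.241 over its alternatives). Among them were smooth muscle actin (Acta2, -4.34, SE 0.36), the myosin light chain Myl9 (-3.46, SE 0.44) and thrombospondin 1 (Thbs1, -3.25, SE 0.54). The list's mean was 10.39 and 10.49 on MSC arrays 1 and 2 and 11.37 and 11.59 on MSC arrays 3 and 4. Of 15 smooth muscle and pericyte markers, 11 fell and 0 rose (11 and 0 adjusted over the list alone), with a median of -2.31 (adjusted p = 3.93e-07, and adjusted p = 0.279 with an estimated correlation, 6.71e-09 to 0.279 over the alternatives). These included Tagln, Cnn1 and Acta2, which the actin list also holds, Lmod1 (-3.87, SE 0.23) and the transcriptional coactivator myocardin (Myocd, -3.70, SE 0.20). The list's mean was 7.65 and 7.87 on MSC arrays 1 and 2 and 8.92 and 9.16 on MSC arrays 3 and 4. Cell cycle genes fell in 24 of 26 cases (25 adjusted over the list alone), with a median of -1.85 (adjusted p = 1.01e-12, and adjusted p = 0.49 with an estimated correlation, 5.3e-18 to 0.49 over the alternatives). Cyclin B1 (Ccnb1, -2.67, SE 0.37) and the mitotic activator Cdc20 (-2.52, SE 0.39) fell furthest. The mean of the list was 6.51 ± 1.11 in dorsal, 6.63 ± 0.18 in facial and 6.21 ± 0.08 in ventral SKPs against 8.15 ± 0.41 in MSCs.

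Targets of FGF, EGF and Wnt signalling shifted upward in SKPs as lists. Of 16 FGF and EGF pathway targets, 8 rose and 1 fell (10 and 2 adjusted over the list alone), with a median of 1.02 (adjusted p = 0.00011, and adjusted p = 0.0521 with an estimated correlation, 8.14e-07 to 0.0521 over the alternatives). The phosphatases Dusp4 (5.12, SE 0.32) and Dusp6 (2.79, SE 0.17), which act on MAP kinases, and the transcription factor Etv1 (2.20, SE 0.16) rose, and Ier3 fell (-0.74, SE 0.12). Of 11 Wnt pathway targets, 8 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 1.39 (adjusted p = 0.000668, and adjusted p = 0.241 with an estimated correlation, 0.000127 to 0.241 over the alternatives). The members that moved included feedback inhibitors of the pathway: Axin2 (2.03, SE 0.31), Notum (1.94, SE 0.36) and Wif1 (1.84, SE 0.29), beside Dkk2 (3.41, SE 0.37). The receptor Lgr5 fell (-1.82, SE 0.52, adjusted p = 0.0232), a call lost without MSC array 1 (0.0782) or MSC array 2 (0.0867) and with the leukocyte signal as a covariate (0.101; 0.00412 to 0.101 over the alternatives).

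Neural crest factors rose in 7 of 17 cases and fell in 3 (7 and 4 adjusted over the list alone), with a median of 0.40 (adjusted p = 0.047). The list's adjusted p = 0.404 with an estimated correlation, and it was 0.0812 without dorsal array 2, 0.0771 without facial array 1, 0.159 without MSC array 1, 0.085 without MSC array 2 and 0.125 among genes above background (0.000808 to 0.404 over the alternatives). Tfap2a (2.57, SE 0.35), an early neural crest transcription factor, rose with Twist1, and the cadherin Cdh6 (1.82, SE 0.18), Zic1 (1.32, SE 0.17) and Pax3 (1.30, SE 0.22) passed because single regions stood high. Macrophage and leukocyte markers rose in 10 of 21 cases and fell in 0 (12 and 0 adjusted over the list alone), with a median of 1.58 (adjusted p = 0.000105, and adjusted p = 0.694 with an estimated correlation). The scavenger receptor Cd68 rose by 3.39 (SE 0.58, adjusted p = 0.0011) and the Fc receptor chain Fcer1g by 2.98 (SE 0.76, adjusted p = 0.0127). Lysozyme 2 (Lyz2) rose by 3.61 (SE 1.00, adjusted p = 0.0196), a call lost without MSC array 3 (0.0585) or MSC array 4 (0.0667), with 0.00329 to 0.403 over the alternatives. With the leukocyte signal as a covariate the list's adjusted p was 0.821 (2.64e-07 to 0.821 over the alternatives), which that fit brings about by construction. The mean of the list differed between isolates of a region: 7.09, 5.05 and 4.21 in dorsal, 7.60, 6.24 and 10.01 in facial and 5.25, 5.29 and 5.54 in ventral SKPs, against 4.20 to 4.70 in MSCs.

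**Figure D3:**
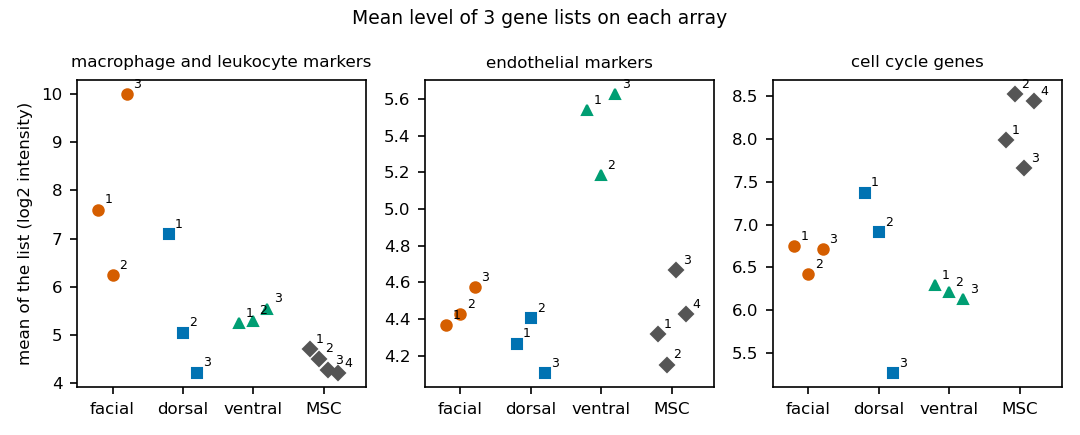
Points are the mean log2 level of the macrophage and leukocyte, endothelial and cell cycle lists on each of the 13 arrays, with the array's number within its group beside them. The leukocyte list is highest on facial array 3 (10.01) and the endothelial list is at 5.19 to 5.63 on the 3 ventral arrays.

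None of the other 26 lists passed the test in SKPs as a class, though single members did. Dermal papilla and dermal sheath markers split: of 24, 8 rose and 4 fell (10 and 5 adjusted over the list alone, median 0.21, adjusted p = 0.203), with Crabp1 and Wnt5a (2.54) up and the growth factor Fgf7 (-2.55) and Ncam1 (-1.89) down. Fibrillar and dermal matrix genes rose in 3 and fell in 4 of 19 cases (3 and 4 over the list alone), and the list's median was -0.22, its mean 0.33 and its test downward (adjusted p = 0.608). Decorin and the crosslinking enzyme Lox (-3.66) were its extremes. Cartilage lineage markers rose in 1 and fell in 3 of 12 cases (1 and 3 over the list alone, median -0.24, adjusted p = 0.203), with Hapln1 up (3.81) and Acan down. Bone lineage markers rose in 3 and fell in 2 of 15 cases (3 and 2 over the list alone, median 0.16, adjusted p = 0.384), with Bmp2 up (3.17) and Phex down (-1.22). Fat lineage markers rose in 4 and fell in 0 of 11 cases (4 and 0 over the list alone, median 0.13, adjusted p = 0.203), led by Cd36 (3.73) and Lpl (3.01). These were 1.83 (adjusted p = 0.0705, 4.11e-05 to 0.0705 over the alternatives) and 1.88 (0.112, 2.53e-06 to 0.112) with the leukocyte signal as a covariate, and lost their calls. Stromal surface markers rose in 4 and fell in 3 of 15 cases (4 and 3 over the list alone, median 0.25, adjusted p = 0.539), among them Alcam (1.60).

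Among markers of other cell types, Schwann and glial markers rose in 3 and fell in 2 of 14 cases (3 and 2 over the list alone, median 0.06, adjusted p = 0.391), with Egr2 (2.24) and Gap43 (1.37) up. Melanocyte markers rose in 3 and fell in 0 of 8 cases (4 and 1 over the list alone, median 0.09, adjusted p = 0.384), with the receptor Kit (2.57) and Mitf (2.25) up. Neuronal markers rose in 2 and fell in 2 of 13 cases (2 and 2 over the list alone, median 0.03, adjusted p = 0.877), with Map2 up (2.59). Keratinocyte markers rose in 1 and fell in 2 of 11 cases (1 and 2 over the list alone, adjusted p = 0.811), and their median (0.01) was positive where the test pointed down. Endothelial markers rose in 6 and fell in 1 of 12 cases (6 and 1 over the list alone, median 0.25, adjusted p = 0.151). Skeletal muscle markers rose in 1 and fell in 4 of 16 cases (1 and 4 over the list alone, median -0.06, adjusted p = 0.468), with the receptor subunit Chrna1 up (2.83) and desmin (Des) down (-2.26).

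None of the position lists passed, nor did the process lists given here. Anterior Hox genes fell in 2 and rose in 0 of 11 cases (1 and 0 over the list alone, median fell by 0.002, adjusted p = 0.662), with Hoxa5 (-1.63, SE 0.12) as the larger, low in facial SKPs alone. Central Hox genes fell in 1 of 3 cases (1 over the list alone, median fell by 0.003, adjusted p = 0.805) and posterior Hox genes in 1 of 8 (1 over the list alone, median -0.13, adjusted p = 0.151), namely Hoxa11 (-3.21, SE 0.48). Craniofacial patterning factors rose in 4 and fell in 2 of 14 cases (4 and 2 over the list alone, median 0.11, adjusted p = 0.391), with Alx4 up (2.75). Somite and dorsal dermis factors rose in 3 and fell in 3 of 10 cases (3 and 3 over the list alone, median -0.11, adjusted p = 0.859), with Meox2 down (-3.49). Lateral plate and ventral body wall factors rose in 3 and fell in 6 of 17 cases (3 and 6 over the list alone, median -0.26, adjusted p = 0.345), with Tbx2 up (2.16). Interferon-stimulated genes rose in 5 and fell in 1 of 19 cases (5 and 1 over the list alone, median 0.08, adjusted p = 0.213), with Usp18 (3.22) and Gbp2 (2.36) up. Cholesterol synthesis genes rose in 4 and fell in 0 of 17 cases (4 and 0 over the list alone, median 0.15, adjusted p = 0.093). Hypoxia and glycolysis genes rose in 1 and fell in 1 of 20 cases (1 and 1 over the list alone, adjusted p = 0.877), with a median that fell by 0.003, a positive mean and an upward test.

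The remaining pathway lists did not pass either. BMP and TGF-beta pathway targets rose in 1 and fell in 3 of 12 cases (1 and 3 over the list alone, median -0.11, adjusted p = 0.447), with the inhibitor Smad6 down (-1.41). Hedgehog pathway targets rose in 1 of 3 cases (2 over the list alone, median 0.37, adjusted p = 0.384). Notch pathway genes rose in 1 and fell in 2 of 13 cases (2 and 2 over the list alone, adjusted p = 0.864), with the ligands Dll1 up (2.21) and Jag1 down (-3.11), a median of 0.01, an upward test and a mean of -0.21. Inflammatory cytokines and chemokines rose in 4 and fell in 1 of 19 cases (4 and 1 over the list alone, median 0.12, adjusted p = 0.391), and the member that fell was Il6 (-2.09). MHC class II genes rose in 2 of 8 cases (2 over the list alone, median 0.59, adjusted p = 0.384). In all, 3672 genes (25.3%) were called between SKPs and MSCs, 1896 higher and 1776 lower in SKPs. Neither direction prevailed: the share of higher calls was 51.6%, and 46.1% after median centring, 45.8% after a further quantile normalisation and 48.4% without MSC array 3. Of these, 671 were higher and 591 lower by at least 2-fold. In 1827 genes (12.6%, against 0.28% by chance) no SKP array overlapped an MSC array. Of the called genes named for this comparison, single arrays overlapped for Ngfr, Vcam1, Snai2, Lgr5, Cd68, Lyz2, Cdh6, Pax3, Zic1, Alcam, Cd36, Lpl, Fgf7, Des, Egr2, Gap43, Kit, Map2 and Hoxa5. With the leukocyte signal as a covariate 2403 genes were called.

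Each region was also set against the same 4 MSC arrays, and the 3 profiles of differences ran in parallel. The regions share the MSC arrays, so their calls are not independent. Both dorsal and facial SKPs had 795 genes called higher and 849 lower, where independent lists would share 120 and 108. Dorsal and ventral SKPs shared 871 higher and 805 lower (166 and 128 by independence), and facial and ventral SKPs 892 and 914 (179 and 158). With separate MSC arrays, and so 2 for each region in place of 4, the calls shared in the same direction fell from 1644 to between 889 and 1070 for dorsal and facial, from 1676 to between 935 and 1194 for dorsal and ventral, and from 1806 to between 1029 and 1238 for facial and ventral SKPs, a drop that does not tell sharing from the smaller number of arrays. All 3 regions shared 681 higher and 689 lower genes, with 16 and 12 by independence. Of 4918 genes called in at least 1 region, 2509 were called in 1 region alone and 30 in opposite directions. Across genes, which are not independent replicates, the differences of 2 regions correlated at r = 0.821 (dorsal with facial), 0.825 (dorsal with ventral) and 0.800 (facial with ventral). Simulated arrays that share the MSCs but hold no difference between groups gave 0.434, 0.429 and 0.427. That r comes from shared noise alone and is not a part of the observed r. The covariance of the differences was 0.488, 0.492 and 0.526, against 0.024 in each simulated case. With separate MSC arrays its mean was 0.456, 0.460 and 0.494, so the shared MSC arrays made up little of it. With separate MSC arrays r lay between 0.622 and 0.789.

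**Figure D4:**
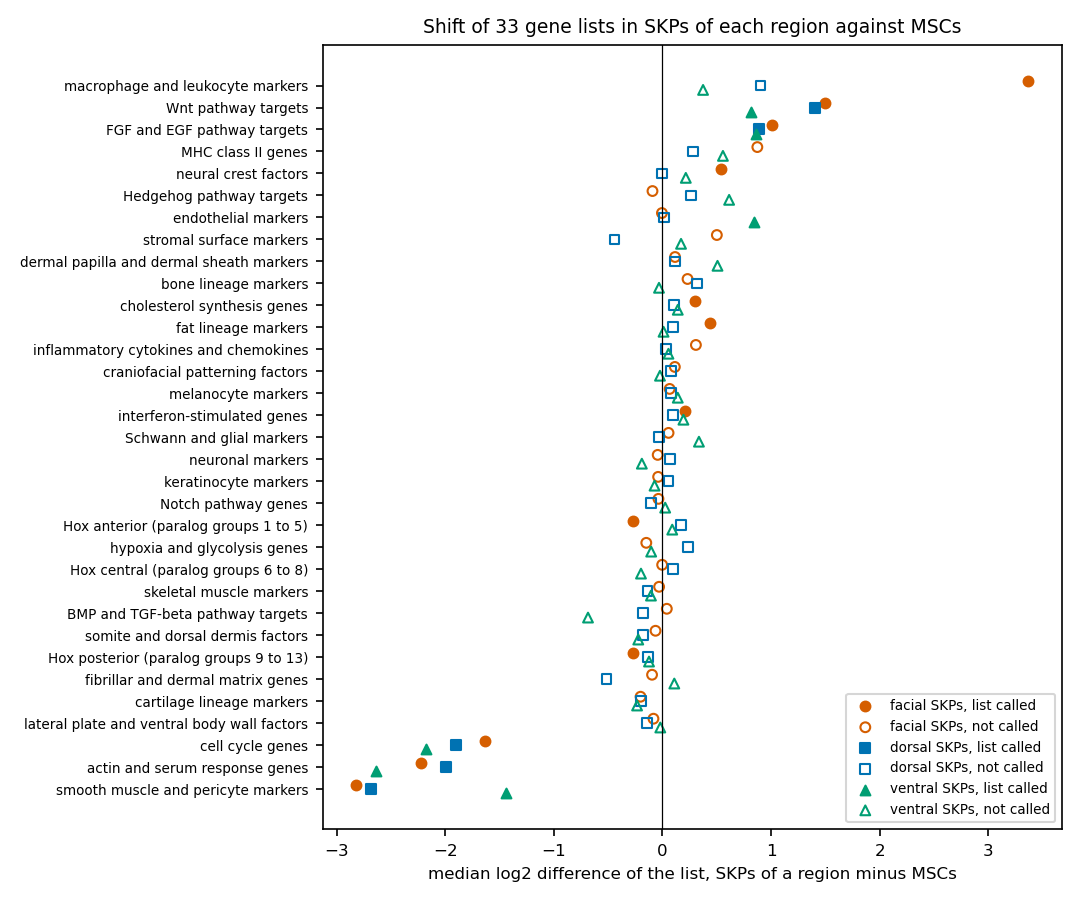
Points are the median log2 difference from MSCs of each of the 33 gene lists in dorsal, facial and ventral SKPs (3 arrays each against 4), filled where camera called the list. Smooth muscle, actin and cell cycle lists lie below 0 and Wnt and FGF targets above 0 in all 3 regions.

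Facial SKPs against MSCs combined high Mmp13 and low Tagln with lower levels of some Hox genes and higher levels of Pax3, Cdh6 and Alx1. Pax3, a neural crest and muscle progenitor factor, stood at 8.68 ± 0.46 in facial SKPs against 4.34 ± 0.49 in MSCs (4.34, SE 0.28, adjusted p = 1.41e-06), and Cdh6 (4.44, SE 0.23, adjusted p = 2.45e-07) and the craniofacial factor Alx1 (2.44, SE 0.26, adjusted p = 6.24e-05) rose with it. Hoxa5 stood at 3.64 ± 0.18, below background, against 7.53 ± 0.25 in MSCs (-3.89, SE 0.15, adjusted p = 7.41e-08). Mmp13 (8.48), Dio2 (8.05), Mmp10 (7.55), Dcn (6.92), Serpina3n (6.31), Bmp7 (6.16), the Wnt modulators Sfrp2 (5.87) and Dkk2 (5.73), and Sparcl1 (5.85) rose as well. Dio2, Mmp10, Serpina3n, Sfrp2, Dkk2, Cdh6 and Alx1 were below background in MSCs, and Hoxa5, Hoxc9 and Hoxa11 in facial SKPs, so the size and rank of these differences are not resolved. Tagln (-7.26), Itga11 (-5.73), Fhl1 (-5.71), Akap12 (-5.65) and the adaptor Grb14 (-4.74) were among the largest decreases. Sox2 (1.51, SE 0.31, adjusted p = 0.00521), Crabp1 (5.01, SE 0.85, adjusted p = 0.00166) and Twist1 (1.71, SE 0.37, adjusted p = 0.00694) rose. With the leukocyte signal as a covariate they lost their calls, at adjusted p = 0.142 (0.00216 to 0.142 over the alternatives), 0.194 (0.000125 to 0.194) and 0.262 (0.00349 to 0.262), with differences of 1.52 for Sox2, 3.39 for Crabp1 and 1.39 for Twist1. The genes named here did not overlap between facial and MSC arrays.

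By list, anterior Hox genes fell in 5 and rose in 0 of 11 cases in facial SKPs (5 and 0 adjusted over the list alone, median -0.27, adjusted p = 0.00095, and adjusted p = 0.139 with an estimated correlation, 4.36e-05 to 0.139 over the alternatives), with Hoxa5 and Hoxc4 (-1.16, SE 0.15) as the steadiest. Craniofacial patterning factors rose in 5 and fell in 2 of 14 cases (6 and 3 over the list alone, median 0.11) and did not pass (adjusted p = 0.197). Posterior Hox genes fell in 2 and rose in 0 of 8 cases, Hoxa11 (-3.21) and Hoxc9 (-2.71), with a median of -0.27 (2 over the list alone, adjusted p = 0.0169). Their adjusted p = 0.139 with an estimated correlation, 0.252 with the leukocyte signal as a covariate and 0.0535 without dorsal array 3 and facial array 3 (8.11e-05 to 0.252 over the alternatives). Neural crest factors rose in 7 and fell in 0 of 17 cases (8 and 1 over the list alone, median 0.54, adjusted p = 0.00361, and adjusted p = 0.139 with an estimated correlation, 8.11e-05 to 0.139). Smooth muscle markers fell in 11 of 15 cases (11 over the list alone, median -2.82, adjusted p = 2.19e-08, and adjusted p = 0.139 with an estimated correlation, 7.29e-10 to 0.139). Actin genes fell in 15 of 17 (17 over the list alone, median -2.22, adjusted p = 2.98e-12, and adjusted p = 0.139 with an estimated correlation, 1.34e-13 to 0.139). Cell cycle genes fell in 21 of 26 (24 over the list alone, median -1.63, adjusted p = 3.25e-10, and adjusted p = 0.474 with an estimated correlation, 1.92e-18 to 0.474). Wnt targets rose in 7 of 11 (8 over the list alone, adjusted p = 0.000997, and adjusted p = 0.139 with an estimated correlation, 0.000229 to 0.139). FGF and EGF targets rose in 8 and fell in 1 of 16 (9 and 1 over the list alone, adjusted p = 1.28e-05), a call that held with an estimated correlation (adjusted p = 0.0269, 2.55e-06 to 0.0269 over the alternatives).

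Leukocyte markers rose in 17 of 21 cases in facial SKPs (19 over the list alone), with a median of 3.37 (adjusted p = 2.48e-10, and adjusted p = 0.402 with an estimated correlation). Lyz2 (6.51, SE 1.27), the oxidase subunit Cybb (6.12, SE 1.23) and the mannose receptor Mrc1 (5.84, SE 1.07) were the largest, and all 3 lost their calls with the leukocyte signal as a covariate, with differences of 1.47, 1.09 and 1.30 at adjusted p = 0.548 (0.000263 to 0.548 over the alternatives), 0.612 (0.000618 to 0.612) and 0.352 (0.000149 to 0.352). The list's mean was 7.95 ± 1.91 in facial SKPs and 4.42 ± 0.23 in MSCs. Fat lineage markers rose in 4 of 11 cases (5 over the list alone, median 0.44, adjusted p = 0.0276, and adjusted p = 0.272 with an estimated correlation), among them Cd36 (4.28) and Lpl (3.22). Without facial array 3 the fat list had an adjusted p of 0.105, Cd36 0.0502 (0.000406 to 0.81 over the alternatives) and Lpl 0.0757 (6.04e-05 to 0.712), and without MSC array 1 the list had 0.0533. Interferon-stimulated genes rose in 5 of 19 cases (5 over the list alone, median 0.21, adjusted p = 0.0282, and adjusted p = 0.522 with an estimated correlation, 0.0136 to 0.522 over the alternatives), led by Usp18 (3.50) and Gbp2 (2.53). That list lost its call without dorsal array 3 (0.052), facial array 3 (0.107) or MSC array 4 (0.0658). Cholesterol synthesis genes rose in 4 of 17 cases (4 over the list alone, median 0.30, adjusted p = 0.00748, and adjusted p = 0.696 with an estimated correlation), with Insig1 up (1.11), and lost the call without MSC array 1 (0.0533). With the leukocyte signal as a covariate the adjusted p was 0.886 for the leukocyte, 0.815 for the fat, 0.427 for the interferon and 0.947 for the cholesterol list, the highest over the alternatives for the first, the second and the fourth, whose lowest were 8.79e-16, 0.0101 and 0.000256. In all 2762 genes (19.0%) were called, 1373 higher and 1389 lower, with 772 and 565 at 2-fold or more and 4366 (30.1%, against 5.71% by chance) without overlap. The covariate left 807.

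Dorsal SKPs against MSCs also had high Mmp13 and low Tagln, and added Zic1. This transcription factor of somites and neural crest stood at 8.11 ± 0.52 in dorsal SKPs against 3.99 ± 0.08 in MSCs (4.12, SE 0.21, adjusted p = 4.03e-07). The arginine synthesis enzyme Ass1 (6.13, SE 0.69, adjusted p = 0.000118), the phosphatase Ptprz1 (6.10, SE 0.34, adjusted p = 6.1e-07) and Lrrc15 (5.47, SE 0.54, adjusted p = 4.52e-05) rose, as did Tfap2a (3.04, SE 0.44, adjusted p = 0.000735). The mesoderm homeobox gene Meox2 fell (-5.06, SE 0.38, adjusted p = 5.73e-06). Mmp13 (8.35), Mmp10 (7.65) and Dcn (7.58) rose, and Tagln (-7.23), Cyp1b1 (-6.17) and Fhl1 (-5.93) fell. Mmp10, Ass1 and Ptprz1 were below background in MSCs and Meox2 in dorsal SKPs, so the size and rank of these differences are not resolved. Sox2 (1.79, SE 0.31, adjusted p = 0.00203), Crabp1 (4.47, SE 0.85, adjusted p = 0.00374) and Twist1 (1.84, SE 0.37, adjusted p = 0.00487) rose, and Ngfr did not pass (0.69, SE 0.27, adjusted p = 0.106). All of the called genes named here lay apart in 3 of 3 dorsal and 4 of 4 MSC arrays.

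In dorsal SKPs smooth muscle markers fell in 10 of 15 cases (11 over the list alone, median -2.69, adjusted p = 1.29e-09, and adjusted p = 0.156 with an estimated correlation, 1.94e-11 to 0.156 over the alternatives). Actin genes fell in 14 of 17 (17 over the list alone, median -1.99, adjusted p = 2.94e-14, and adjusted p = 0.156 with an estimated correlation, 1.62e-15 to 0.156). Cell cycle genes fell in 21 of 26 (23 over the list alone, median -1.90, adjusted p = 4.7e-12, and adjusted p = 0.618 with an estimated correlation, 1.09e-16 to 0.618). Without dorsal array 3 and facial array 3 the cell cycle median was -1.02. Wnt targets rose in 7 of 11 (8 over the list alone, median 1.41, adjusted p = 0.000396, and adjusted p = 0.156 with an estimated correlation, 9.99e-05 to 0.156). FGF and EGF targets rose in 8 and fell in 1 of 16 (10 and 1 over the list alone, median 0.89, adjusted p = 0.000102), a call that held with an estimated correlation (adjusted p = 0.0473, 2.22e-05 to 0.0473). Somite and dorsal dermis factors rose in 2 and fell in 3 of 10 cases (2 and 4 over the list alone, median -0.18) and did not pass (adjusted p = 0.493). Leukocyte markers did not pass (median 0.90, camera adjusted p = 0.0973), with 0 of 21 called by limma and 2 at an unadjusted p under 0.05. In all 2397 genes (16.5%) were called, 1272 higher and 1125 lower, with 557 and 552 at 2-fold or more, and 3259 (22.5%, against 5.71% by chance) showed no overlap. A fit on the dorsal and MSC arrays alone called 1250.

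Ventral SKPs against MSCs added endothelial genes and single regional factors to high Mmp13 and low Tagln. Tbx5, a lateral plate and forelimb field factor, stood at 6.33 ± 0.26 against 4.17 ± 0.27 in MSCs (2.16, SE 0.19, adjusted p = 1.27e-05). The endothelial adhesion molecule Pecam1 (2.63, SE 0.33, adjusted p = 0.000176), endomucin (Emcn, 2.42, SE 0.26, adjusted p = 4.95e-05) and the VEGF receptor Flt1 (2.28, SE 0.52, adjusted p = 0.00746) rose. So did the Wnt antagonist Frzb (5.77, SE 0.26, adjusted p = 8.31e-08) and the transcription factor Egr2 (4.71, SE 0.47, adjusted p = 2.95e-05). Car2 (7.85), the lysophospholipase Enpp2 (6.76) and Cpxm1 (6.57) rose beside Mmp13 (8.49) and Dcn (8.15), and Tagln (-7.75), Itga11 (-5.93), Acan (-5.88) and Ogn (-5.67) fell. Car2, Enpp2, Emcn, Pecam1 and RT1-Da were below background in MSCs, so the size and rank of their differences are not resolved. Sox2 (1.81, SE 0.31, adjusted p = 0.00123), Crabp1 (5.14, SE 0.85, adjusted p = 0.000997), Twist1 (1.61, SE 0.37, adjusted p = 0.00707) and Ngfr (1.72, SE 0.27, adjusted p = 0.000669) rose, and so did the MHC class II genes RT1-Da (4.21, SE 0.97) and Cd74 (3.93, SE 0.93). Nes rose by 1.98 (SE 0.52, adjusted p = 0.0153), a call lost without ventral array 1 (0.0533) or ventral array 3 (0.0509), with an adjusted p of 0.000559 to 0.0533 over the alternatives. The genes named here did not overlap between ventral and MSC arrays.

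Endothelial markers rose in 7 and fell in 1 of 12 cases in ventral SKPs (7 and 1 over the list alone, median 0.84, adjusted p = 0.000421, and adjusted p = 0.289 with an estimated correlation, 1.73e-05 to 0.289 over the alternatives). Cell cycle genes fell in 22 of 26 (23 over the list alone, median -2.18, adjusted p = 2.4e-11, and adjusted p = 0.511 with an estimated correlation, 6.81e-17 to 0.511). Actin genes fell in 16 of 17 (16 over the list alone, median -2.64, adjusted p = 2.47e-12, and adjusted p = 0.289 with an estimated correlation, 9.76e-14 to 0.289). Smooth muscle and pericyte markers fell in 6 and rose in 1 of 15 (9 and 2 over the list alone, median -1.44, adjusted p = 0.000843, and adjusted p = 0.511 with an estimated correlation, 5.27e-05 to 0.511), and the member that rose was the pericyte marker Rgs5 (1.17). FGF and EGF targets rose in 8 and fell in 2 of 16 (8 and 2 over the list alone, median 0.86, adjusted p = 0.00316, and adjusted p = 0.185 with an estimated correlation, 7.2e-06 to 0.185). Wnt targets rose in 6 and fell in 0 of 11 (6 and 1 over the list alone, median 0.82, adjusted p = 0.0123), with adjusted p = 0.457 with an estimated correlation and 0.0538 among genes above background (0.00255 to 0.457). Leukocyte markers rose in 3 of 21 and the list did not pass (median 0.37, adjusted p = 0.165). Lateral plate and ventral body wall factors rose in 3 and fell in 6 of 17 cases (4 and 6 over the list alone, median -0.02) and did not pass (adjusted p = 0.78). In all 3545 genes (24.4%) were called, 1891 higher and 1654 lower, with 751 and 637 at 2-fold or more, and 5493 (37.9%, against 5.71% by chance) showed no overlap.

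Between regions, facial SKPs were set against the trunk mean of dorsal and ventral SKPs. Leukocyte markers shifted most as a list (median 2.89). Of positional genes, 7 of 11 anterior Hox genes fell in facial SKPs, and Pax3, Alx1, Lhx6, Msx1 and Cdh6 rose. None of the lists that hold these 5 was called by camera in this comparison. The mean of the craniofacial factors overlapped, at 5.50 on facial array 3 and 5.58 on dorsal array 2. The mean of the somite and dorsal dermis factors was higher in facial (5.57 to 5.81) than in dorsal SKPs (5.21 to 5.42). Neural crest factors, among them Pax3, Msx1 and Cdh6, had a mean of 6.28 to 6.67 in facial and 5.76 to 6.15 in trunk SKPs. Hoxa5 stood at 3.64 ± 0.18 in facial, 6.89 ± 0.15 in dorsal and 7.18 ± 0.19 in ventral SKPs (-3.39, SE 0.14, adjusted p = 3.75e-07). Hoxc9 (-3.35, SE 0.19, adjusted p = 2.71e-06) was at 3.38 ± 0.23 in facial SKPs, below background, and Hoxc5 (-2.08, SE 0.31, adjusted p = 0.00422) and Hoxc4 (-1.73, SE 0.14, adjusted p = 5.56e-05) fell too. Pax3 stood at 8.68 ± 0.46 in facial against 4.23 ± 0.35 in dorsal and 4.02 ± 0.16 in ventral SKPs (4.56, SE 0.26, adjusted p = 2.31e-06). Cdh6 (3.94, SE 0.21, adjusted p = 2.12e-06), Alx1 (2.36, SE 0.24, adjusted p = 0.000449), Msx1 (2.27, SE 0.23, adjusted p = 0.000454) and Lhx6 (1.49, SE 0.15, adjusted p = 0.000454) rose in 3 of 3 facial arrays over all 6 trunk arrays. The neuronal adhesion protein Cntn6 (4.25) and Emb (3.59) rose. The receptor Adgrl4 (-3.25), the coagulation inhibitor Tfpi (-2.51), Mdga2 (-2.14) and Slc43a3 (-2.14) fell. Hoxa5, Hoxc9, Hoxc5, Adgrl4 and Mdga2 were below background in facial and Cntn6 in trunk SKPs, so the size and rank of these differences are not resolved. Sox2 (-0.30, SE 0.29, adjusted p = 0.661), Crabp1 (0.21, SE 0.78, adjusted p = 0.926) and Twist1 (-0.02, SE 0.34, adjusted p = 0.984) did not pass.

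**Figure D5:**
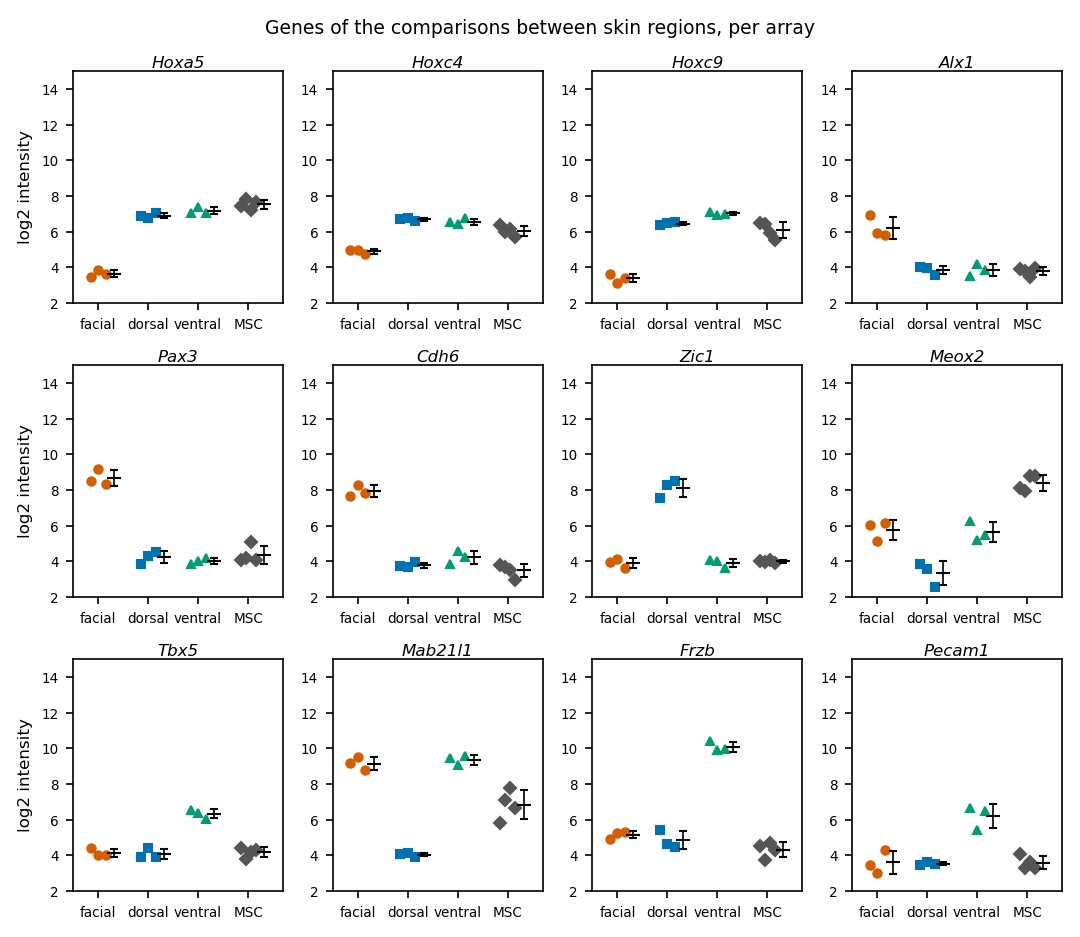
Points are single arrays and bars are the mean and SD of each group (3 arrays per SKP region, 4 of MSCs) for 12 genes that differ between regions, in log2 expression. Hoxa5, Hoxc4 and Hoxc9 are low and Pax3, Alx1 and Cdh6 high in facial SKPs, Zic1 is high in dorsal SKPs, and Tbx5, Frzb and Pecam1 are high in ventral SKPs.

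Of 11 anterior Hox genes, 7 fell and 0 rose in facial against trunk SKPs (8 and 0 adjusted over the list alone), with a median of -0.59 (adjusted p = 5.34e-10). The call held with an estimated correlation (adjusted p = 0.0444, 3.87e-11 to 0.0444 over the alternatives). Leukocyte markers rose in 3 of 21 cases (18 over the list alone), with a median of 2.89 (adjusted p = 6.13e-13, and adjusted p = 0.457 with an estimated correlation). Without facial array 3 that median was 1.54, and with the leukocyte signal as a covariate the list's adjusted p was 0.901 (6.82e-22 to 0.901 over the alternatives). Stromal surface markers rose in 2 of 15 cases (2 over the list alone, median 0.38, adjusted p = 0.00976, and adjusted p = 0.469 with an estimated correlation, 0.00165 to 0.469), namely the leukocyte adhesion molecule Vcam1 (3.98) and the adhesion molecule Alcam (2.02). The list lost its call without dorsal array 3 (0.11). With the covariate their differences did not shrink, but Vcam1 had an adjusted p of 0.0774 (0.00143 to 0.0774) and Alcam (2.07) 0.0717 (0.000394 to 0.0717). Endothelial markers fell in 2 of 12 cases (4 over the list alone, median -0.32, adjusted p = 0.00976, and adjusted p = 0.457 with an estimated correlation, 0.000373 to 0.457), where ventral arrays alone stood high. In all 391 genes (2.70%) were called, 185 higher and 206 lower, with 116 and 57 at 2-fold or more, and 1099 (7.58%, against 2.38% by chance) showed no overlap. The count was 217 without facial array 1, 150 without facial array 3, 149 without ventral array 1, 170 without ventral array 2, 169 without ventral array 3, and 57 with the leukocyte signal as a covariate. The share of calls that were higher was 47.3%, and lay between 36.6% (without dorsal array 2) and 67.6% (without facial array 2) with 1 array left out.

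Facial against dorsal SKPs differed in single positional factors and gave the fewest calls of the 8 comparisons. Zic1 stood at 3.91 ± 0.28 in facial and 8.11 ± 0.52 in dorsal SKPs (-4.20, SE 0.23, adjusted p = 3.88e-06), and Hoxa5 (-3.25, SE 0.16, adjusted p = 3.19e-06), Hoxc9 (-3.07, SE 0.22, adjusted p = 2.18e-05) and Hoxc4 (-1.80, SE 0.16, adjusted p = 0.000135) fell in facial SKPs. Mab21l1 stood at 9.15 ± 0.37 in facial and 4.04 ± 0.10 in dorsal SKPs (5.11, SE 0.38, adjusted p = 2.28e-05), and at 9.34 ± 0.27 in ventral SKPs, so it was low in dorsal SKPs and not particular to facial ones. Pax3 (4.45, SE 0.30, adjusted p = 1.09e-05), Cntn6 (4.18, SE 0.36, adjusted p = 0.000122) and Cdh6 (4.17, SE 0.24, adjusted p = 5.7e-06) rose. Adgrl4 (-4.15), Tfpi (-2.41), the cadherin Cdh7 (-2.36) and the sulfatase Sulf1 (-2.20) fell. Adgrl4, Cdh7, Hoxa5 and Hoxc9 were below background in facial and Cdh6 and Cntn6 in dorsal SKPs, so the size and rank of these differences are not resolved. These genes did not overlap between the 3 facial and 3 dorsal arrays, and Sox2 (-0.29, SE 0.33, adjusted p = 0.741), Crabp1 (0.55, SE 0.91, adjusted p = 0.832) and Twist1 (-0.13, SE 0.39, adjusted p = 0.912) did not pass.

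By list, anterior Hox genes fell in 5 of 11 cases in facial against dorsal SKPs (8 over the list alone), with a median of -0.63 (adjusted p = 3.33e-11). The call held with an estimated correlation (adjusted p = 0.0302, 3.98e-12 to 0.0302 over the alternatives). Neural crest factors rose in 3 and fell in 1 of 17 cases (5 and 1 over the list alone, median 0.40, adjusted p = 0.00135, and adjusted p = 0.281 with an estimated correlation, 0.000281 to 0.281). Leukocyte markers were called in 0 of 21 cases by limma (17 higher over the list alone and 17 at an unadjusted p under 0.05), yet the list passed with a median of 2.72 (adjusted p = 7.67e-13, and adjusted p = 0.357 with an estimated correlation). With the leukocyte signal as a covariate its adjusted p was 0.768 (5.04e-22 to 0.768 over the alternatives), and single members such as Lyz2 (3.79, SE 1.36, adjusted p = 0.235) varied between isolates. Interferon-stimulated genes passed as a list (median 0.35, adjusted p = 0.00105, and adjusted p = 0.357 with an estimated correlation, 0.000303 to 0.357), with 0 of 19 called by limma, 0 over the list alone and 3 at an unadjusted p under 0.05, and had an adjusted p of 0.0896 with the covariate. Stromal surface markers rose in 2 of 15 cases, Vcam1 (4.48) and Alcam (1.91), with a median of 0.48 (2 over the list alone, adjusted p = 3.11e-05, and adjusted p = 0.29 with an estimated correlation, 4.38e-06 to 0.29). Alcam had an adjusted p of 0.0533 without facial array 3 (0.00193 to 0.138 over the alternatives). Matrix genes rose in 1 of 19 cases (1 over the list alone, median 0.42, adjusted p = 0.0266, and adjusted p = 0.67 with an estimated correlation, 0.000837 to 0.791). That list turned to -0.10 without dorsal array 3 (0.604) and had an adjusted p of 0.0639 without facial array 1. In all 182 genes (1.25%) were called, 115 higher and 67 lower, with 89 and 38 at 2-fold or more, and 2522 (17.4%, against 10% by chance) showed no overlap. The count was 94 without facial array 3, 121 without ventral array 1, 43 in a fit on these 6 arrays alone, and 38 with the leukocyte signal as a covariate. The share of calls that were higher was 63.2%, and 46.1% without dorsal array 2.

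Facial against ventral SKPs differed in leukocyte markers, in Hox and other positional genes, in endothelial genes and in single secreted factors. By the naming rule, the largest rises in facial SKPs were the leukocyte markers Mrc1 (5.54, SE 1.14, adjusted p = 0.0155) and Cybb (5.37, SE 1.31, adjusted p = 0.0317). Frzb stood at 10.08 ± 0.27 in ventral and 5.16 ± 0.22 in facial SKPs (-4.92, SE 0.28, adjusted p = 2.99e-06). The guidance factor Sema3d (-4.49, SE 0.48, adjusted p = 0.000432), the chemokine receptor Ccr2 (-3.67, SE 0.21, adjusted p = 2.99e-06), Hoxc9 (-3.64, SE 0.22, adjusted p = 5.46e-06), Hoxa5 (-3.54, SE 0.16, adjusted p = 1.2e-06) and Tbx5 (-2.18, SE 0.20, adjusted p = 0.000156) were lower in facial SKPs. Emb (5.16, SE 0.41, adjusted p = 3.57e-05), Pax3 (4.66, SE 0.30, adjusted p = 5.52e-06), Cntn6 (4.32), Sfrp2 (4.23), Bmp3 (4.07), Scin (4.05) and Cdh6 (3.71) were higher. Ccr2, Hoxa5 and Hoxc9, and the endothelial Pecam1 and Emcn, were below background in facial and Cntn6 in ventral SKPs, so the size and rank of these differences are not resolved. Nes fell in facial SKPs (-2.74, SE 0.56, adjusted p = 0.0142). Its call was lost without facial array 3 (0.0537), ventral array 1 (0.0554) or ventral array 3 (0.0544) and with the leukocyte signal as a covariate (0.146), with 0.000903 to 0.146 over the alternatives. All these genes lay apart in 3 of 3 and 3 of 3 arrays, and Sox2 (-0.30, SE 0.33, adjusted p = 0.658), Crabp1 (-0.13, SE 0.91, adjusted p = 0.962) and Twist1 (0.09, SE 0.39, adjusted p = 0.93) did not pass.

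Anterior Hox genes fell in 5 and rose in 0 of 11 cases in facial against ventral SKPs (8 and 1 over the list alone, median -0.50, adjusted p = 9.85e-07, and adjusted p = 0.0895 with an estimated correlation, 1.01e-07 to 0.0895 over the alternatives). Endothelial markers fell in 4 of 12 cases (5 over the list alone, median -0.68, adjusted p = 9.85e-07, and adjusted p = 0.0895 with an estimated correlation, 1.81e-08 to 0.0895), led by Pecam1 (-2.60, SE 0.36) and Emcn (-2.45, SE 0.28). Leukocyte markers rose in 5 and fell in 0 of 21 cases (16 and 1 over the list alone, median 3.06, adjusted p = 8.91e-08, and adjusted p = 0.744 with an estimated correlation), and the covariate brought the list to an adjusted p of 0.856 (1e-14 to 0.856 over the alternatives). In all 958 genes (6.60%) were called, 326 higher and 632 lower, with 153 and 169 at 2-fold or more, and 5278 (36.4%, against 10% by chance) showed no overlap. The count was 610 without facial array 1, 515 without facial array 3, 390 without ventral array 1, 479 without ventral array 2, 394 without ventral array 3, 284 with the leukocyte signal as a covariate and 1932 in a fit on these 6 arrays alone. The share of calls that were higher was 34.0%, and 44.6% after cyclic loess.

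Dorsal against ventral SKPs separated the trunk regions by Zic1 on the dorsal side and by Frzb, Tbx5 and endothelial genes on the ventral side. Zic1 stood at 8.11 ± 0.52 in dorsal and 3.91 ± 0.23 in ventral SKPs (4.19, SE 0.23, adjusted p = 2.65e-06), and Emb (3.15, SE 0.41, adjusted p = 0.00152), Cdh7 (2.59, SE 0.23, adjusted p = 0.000108) and Ptprz1 (2.33, SE 0.36, adjusted p = 0.00406) were higher in dorsal SKPs. Mab21l1 (-5.30, SE 0.38, adjusted p = 1.93e-05), Frzb (-5.24, SE 0.28, adjusted p = 2.65e-06), Cpxm1 (-4.69, SE 0.83, adjusted p = 0.0087), Egr2 (-4.17, SE 0.50, adjusted p = 0.000848), Ccr2 (-3.79, SE 0.21, adjusted p = 2.65e-06) and collagen XIV (Col14a1, -3.41, SE 0.41, adjusted p = 0.000926) were lower. Tbx5 (-2.27, SE 0.20, adjusted p = 0.000113), Meox2 (-2.30, SE 0.41, adjusted p = 0.00847), Notch1 (-2.16, SE 0.34, adjusted p = 0.00424) and Nes (-3.23, SE 0.56, adjusted p = 0.00732) were lower too. Hoxa5 (-0.29, SE 0.16, adjusted p = 0.343) and Hoxc9 (-0.57, SE 0.22, adjusted p = 0.163) did not pass, nor did Sox2 (-0.02, SE 0.33, adjusted p = 0.987), Crabp1 (-0.68, SE 0.91, adjusted p = 0.732) or Twist1 (0.23, SE 0.39, adjusted p = 0.8). The called genes named here did not overlap between the 3 dorsal and 3 ventral arrays. Ccr2 and Meox2, and the endothelial Pecam1, Emcn and Kdr, were below background in dorsal and Cdh7 in ventral SKPs, so the size and rank of these differences are not resolved.

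Endothelial markers fell in 4 of 12 cases in dorsal against ventral SKPs (8 over the list alone), with a median of -0.98 (adjusted p = 4.39e-09, and adjusted p = 0.0593 with an estimated correlation, 2.42e-11 to 0.0593 over the alternatives). Pecam1 stood at 6.19 ± 0.66 in ventral against 3.53 ± 0.08 in dorsal SKPs (-2.67, SE 0.36), and Emcn (-2.45, SE 0.28), Kdr (-1.45, SE 0.19) and Cdh5 (-0.92, SE 0.11) fell with it. Schwann and glial markers fell in 2 of 14 cases (6 over the list alone, median -0.42, adjusted p = 0.0081, and adjusted p = 0.863 with an estimated correlation, 0.00171 to 0.863), Egr2 and Gap43 (-1.65, SE 0.30). Matrix genes fell in 1 of 19 cases (1 over the list alone, median -0.59, adjusted p = 0.0081, and adjusted p = 0.863 with an estimated correlation, 0.000153 to 0.883), and without dorsal array 3 their median was -0.18 (adjusted p = 0.883). In all 886 genes (6.11%) were called, 341 higher and 545 lower, with 68 and 215 at 2-fold or more, and 4170 (28.7%, against 10% by chance) showed no overlap. The count was 334 without ventral array 1, 465 without ventral array 2, 327 without ventral array 3 and 373 in a fit on these 6 arrays alone.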

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

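The 2 tests of the leukocyte pattern were chosen after the result was seen. A test of cell cycle dilution was exchanged for another, as told below, and the other tests here were written before their results.

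Leukocyte markers were higher in SKPs than in MSCs, and their level differed between isolates of a region. If leukocytes were present in differing amounts, their markers would rise and fall as 1 block: over deviations from region means in the 9 SKP arrays, the median pairwise r of the 21 measured markers was 0.893, where the 95th percentile of 1000 random lists of like spread was 0.761. Without facial array 3 the facial minus trunk median was 1.54 (2.89 with it, median SE 0.623), so a shift remained. The value lay just past the bound of 1.5, which was set after the levels were known. The mean of the list on dorsal array 1 (7.09) was above that on facial array 2 (6.24). This test therefore does not decide whether facial array 3 alone set facial apart from trunk SKPs. The list's mean was 4.20 to 4.70 in MSCs. It was higher on facial arrays 1 (7.60) and 2 (6.24), dorsal arrays 1 (7.09) and 2 (5.05) and all ventral arrays (5.25 to 5.54). Dorsal array 3 (4.21) lay within the MSC range. These levels, compared without a planned test, argue against facial array 3 alone as the source of the higher level in SKPs than in MSCs. Leukocytes carried along in some cultures are a candidate explanation, and their abundant transcripts stood high in facial SKPs: Lyz2 at 11.02 ± 1.64, Cybb at 10.64 ± 1.82 and Cd68 at 10.29 ± 1.28, against 4.51 ± 0.94, 4.52 ± 0.99 and 5.53 ± 0.55 in MSCs. Expression of these genes by SKPs themselves stays open, and 1 of the 21 markers is also in another list. In MSCs 17 of the 21 markers were above background too. Background is a low percentile of a group's own means, so most genes lie above it by construction. That count therefore does not show that MSCs express these markers.

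Anterior Hox genes were lower in facial than in trunk SKPs, with a median of -0.79 over the 7 called members. These members were picked by their call in the same arrays, which favours a low median, and the median of the whole list, given above, was smaller in size. With the leukocyte signal as a covariate the median of the 7 was -0.79 (median SE 0.196). For these genes that argues against differing leukocyte content, and the whole list kept its call with this covariate. Without dorsal array 3 and facial array 3 the median of the 7 was -0.85 (median SE 0.164), which for these genes argues against those arrays as the source. A difference by skin region, which the design names, may explain it and was not tested apart from these arrays.

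Cell cycle genes were lower in SKPs than in MSCs, with a median of -1.85 over 26 genes. The first test written for dilution by leukocytes, the facial minus dorsal median, gave 0.11 (median SE 0.457) and left it undecided. It was exchanged, with that value known, for the fit with the leukocyte signal as a covariate, which gave -2.48 (median SE 0.395). That fit leans on the spread within regions. There dorsal array 3, which stood apart, was low in leukocyte markers (4.21, dorsal array 1 at 7.09) and cell cycle genes (5.26, 7.37). The fit therefore does not decide on dilution. Ventral SKPs had the lowest mean of the SKP regions for leukocyte markers (5.36 ± 0.16) and for cell cycle genes (6.21 ± 0.08). These levels, compared without a planned test, argue against dilution in ventral SKPs. MSC arrays of 1 pair as the source are argued against as well, at -1.63 without MSC arrays 1 and 2 and -2.02 without MSC arrays 3 and 4 (median SE 0.457). Culture conditions are not given in the sources used here and are not separable from cell type, so the lower level of these transcripts may reflect either. Division itself was not measured, and the list's adjusted p = 0.49 with an estimated correlation (5.3e-18 to 0.49 over the alternatives).

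Other splits of the same arrays into groups of the same sizes were counted. For SKPs against MSCs 1 of 100 splits, the real one, gave as many genes (2861 in a fit of 9 arrays against 4, highest other 117). Each region against MSCs had 35 splits, of which 1, the real one, gave as many. The counts were 2762 for facial (highest other 510), 2397 for dorsal (highest other 567) and 3545 for ventral SKPs (highest other 694). For these 4 comparisons the share was under 0.05. Every other split mixes SKP and MSC arrays in a group, which widens the spread within groups and lowers its count. Chance is therefore not excluded by these counts. For facial against dorsal (182, highest other 2), facial against ventral (958, highest other 0) and dorsal against ventral SKPs (886, highest other 0) the 10 splits are too few for a share under 0.05, and 1 split, the real one, gave as many. For facial against trunk SKPs 2 of 84 splits gave as many (127 in a fit of 3 arrays against 6), a share under 0.05. The other split was the 3 ventral arrays against the rest and gave more (827), which points to a structure of the samples. The count therefore does not single out the facial group.

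Of 172 levels tested in the 4 MSC arrays, 7 had 1 array far from the others, where chance gives about 1 in 20. The gap as a share of the range was 0.879 for Car2 (2.97 on MSC array 2, others 4.04 to 4.19), 0.901 for Cpxm1 (3.89 on MSC array 4, others 4.50 to 4.57) and 0.84 for Enpp2 (3.61 on MSC array 3, others 3.19 to 3.26). It was 0.831 for Il6 (4.16 on MSC array 2, others 5.52 to 5.80), 0.872 for Ncam1 (8.87 on MSC array 2, others 9.26 to 9.32) and 0.873 for Pax3 (5.07 on MSC array 3, others 4.05 to 4.18). For the mean of the Wnt pathway targets it was 0.891 (5.34 on MSC array 1, others 5.23 to 5.24).

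Some genes differed from MSCs unlike in 2 regions, by the tested difference between the regions. Mab21l1 differed by -5.30 between dorsal and ventral and by -5.11 between dorsal and facial SKPs. Between facial and ventral SKPs the differences were 5.16 for Emb, -4.49 for Sema3d, -3.64 for Hoxc9, -2.60 for Tfpi, 1.91 for Msx1, 1.87 for Hlx and -1.67 for Hoxc4. Between dorsal and facial SKPs they were -2.64 for Msx1, 2.41 for Tfpi, 1.80 for Hoxc4 and -1.71 for Hlx, and Col14a1 differed by -3.41 between dorsal and ventral SKPs.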

How the results depend on the processing

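The alternatives with the leukocyte signal as a covariate, and with dorsal array 3 and facial array 3 left out, were chosen after the data were seen. Of 12834 recomputed values of named genes and lists, 11930 kept direction and side of the threshold, 863 lost their call, 36 gained one and 5 reversed. The cause was not tested unless stated.

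Comparisons follow in the order SKPs, facial, dorsal and ventral against MSCs, facial against dorsal, facial against ventral, dorsal against ventral, facial against trunk. At an adjusted p under 0.01 the counts were 2281, 1425, 1310, 2096, 64, 298, 238 and 99. With a 2-fold minimum they were 1262, 1337, 1109, 1388, 127, 322, 283 and 173. Both follow from stricter thresholds. With an estimated correlation 4 of 46 list calls held. Fry called 64 lists, 36 of them shared with the 46, and of the named list values 9 gained and 10 lost a call.

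All probe sets gave 1460 (facial against ventral) and 1410 (dorsal against ventral), and genes above the median 104 (facial against dorsal). Array weights gave 2441 (facial against ventral), 1519 (dorsal against ventral) and 690 (facial against trunk). Fits on the compared groups alone, with fewer arrays, gave 1250 (dorsal against MSCs), 43 (facial against dorsal), 1932 (facial against ventral) and 373 (dorsal against ventral).

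A block for the sample number gave 106 (facial against dorsal), 566 (dorsal against ventral) and 173 (facial against trunk). The numbers did not pair the arrays: 1 of 18 pairs with the same number had r above 0.1.

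The leukocyte covariate gave 2403 (SKPs against MSCs), 807 (facial against MSCs), 38 (facial against dorsal), 284 (facial against ventral) and 57 (facial against trunk). Without dorsal array 3 and facial array 3 the counts were 99 (facial against dorsal) and 212 (facial against trunk).

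With 1 array left out, counts ran from 2964 to 4025, 1898 to 3288, 1920 to 2301, 2545 to 4072, 94 to 258, 390 to 1416, 327 to 937 and 149 to 524, and list calls from 45 to 61.

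Matrix genes in facial against dorsal SKPs turned to -0.095 without dorsal array 3 (0.745 without dorsal array 1) and to -0.057 without dorsal array 3 and facial array 3. With the covariate, Fabp4 in facial SKPs against MSCs turned to -0.373, and the leukocyte list to -0.239 in SKPs and -0.145 in facial SKPs against MSCs, as a covariate made from that list brings about.

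The share of higher calls moved by over 10 points in 4 comparisons. From 47.3%, facial against trunk went to 35.5% after median centring, 59.4% after cyclic loess, 36.8% above the median level, 67.1% at 2-fold, 36.6% without dorsal array 2 and 57.6%, 67.6% and 61.3% without facial arrays 1, 2 and 3. From 34.0%, facial against ventral went to 44.6% after cyclic loess, 47.5% at 2-fold and 46.2% without facial array 2. From 38.5%, dorsal against ventral went to 22.3% at an adjusted p under 0.01, 24.0% at 2-fold and 23.5% without ventral array 3. From 63.2%, facial against dorsal went to 46.1% without dorsal array 2.

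In the comparisons with MSCs, where higher and lower calls were near even, the majority turned. From 51.6%, SKPs went to 46.1% (median centring), 45.8% (quantile normalisation again), 49.3% (array weights), 49.5% (all probe sets) and 48.4% (without MSC array 3). From 49.7%, facial SKPs went to between 40.8% (median centring) and 57.7% (2-fold). From 53.1%, dorsal SKPs went to 49.4%, 47.9% and 48.4% (median centring, quantile normalisation, cyclic loess) and 48.6% (without MSC array 3), and from 53.3%, ventral SKPs to 49.0% (quantile normalisation).

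Genes above background numbered 11325 of 14506, which limits what can be seen below it.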

Other observations

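The gene families here, grouped by symbol, were chosen after their values were seen. Matrix metalloproteinases (Mmp, 21 members) rose in 11 and fell in 1 case in SKPs against MSCs, with a median of 0.73 (camera adjusted p = 0.000288, and 0.828 with an estimated correlation), among them Mmp12 (4.86) and Mmp11 (3.77). Kinesins (Kif, 29 members) rose in 3 and fell in 14 cases, with a median of -0.41 (adjusted p = 0.00311, and 0.797 with an estimated correlation), among them Kif4a (-2.94) and Kif23 (-2.60). Wnt ligands (17 members) rose in 8 and fell in 0 cases, with a median of 0.26 (adjusted p = 0.0404, and 0.969 with an estimated correlation), among them Wnt7b (2.74) and Wnt16 (2.70). C-type lectins (Clec, 29 members) rose in 4 cases in facial against ventral SKPs, with a median of 0.49 (adjusted p = 0.000242, and 0.672 with an estimated correlation), led by the myeloid receptor Clec7a (3.85), and leukocyte markers rose in the same comparison (median 3.06). The family also passed in facial against trunk (median 0.40, adjusted p = 1.84e-06, and 0.468 with an estimated correlation) and facial against dorsal SKPs (0.42, adjusted p = 0.000156, and 0.778), with 0 members called by limma and 15 and 9 at an unadjusted p under 0.05. These directions were the same under the 3 other scalings.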
